A study of Drosophila melanogaster with 3 samples.

How the data were processed

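The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of 1 group of samples, 3 biological replicates of whole Drosophila melanogaster embryos of 0 to 24 hours. Per the labels, the flies carried a transgene for hat-trick (htk, also CG34422) fused to eGFP by an insertion directed at htk, chromatin was sheared by sonication, and the fusion protein was pulled down with an antibody against GFP. Replicate numbers come from the labels. No other genotype, antibody or stage was labelled, so no group was set against another, and an anti-GFP ChIP from flies without the fusion was not used here.

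The files used were peak lists on the dm6 assembly, per the labels. Each replicate had its own list of candidate peaks ranked by irreproducible discovery rate (IDR) and a thresholded list, and the whole series had 4 such pairs of lists, of which the submitters call 1 conservative. The aligner and the peak caller are not given in the sources used here, and signal tracks and alignments were not used here. The deposited file descriptions derive the lists from filtered alignments and a control file, which was not used here, and the series-level lists from the alignments of all 3 replicates. Read depth is not given in the files used, so depth is unknown and the precision of single peak values cannot be stated; the number of candidates and of listed peaks per replicate stands in the report. The authors give each peak a signal value, which is used to describe, rank or filter peaks inside 1 list, and across lists only to tell which records are shared. The deposited score column is an IDR score of at most 1000, at least 830 in the thresholded lists. The ranked lists also hold the authors' −log10 of the IDR, and the thresholded lists hold records with −log10 IDR of at least 2, an IDR of 0.01. Some records past that value are missing from the thresholded lists (222 of 4684 for the conservative list), so a further filter was applied by the authors, whose nature is not given in the sources used here; such records entered neither the peak set nor the background. Column 8 is -1 in all lists and was not used.

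The ranked list behind each series-level list carries, beside each record, the coordinates and signal of the peak in the 2 lists compared. For the conservative list 81223 of 123916 records matched a candidate of replicate 2 exactly in the first of these and 87470 matched replicate 3 in the second, and 0 matched replicate 1. By this record match the conservative list compares replicates 2 and 3, other lists compare replicates 1 and 2 and replicates 1 and 3, and a last list matches no replicate and is called the pooled list here. The highest signal is the same in all 4 series-level lists (2715), above that of each own list, so their records were taken to come from calls on reads of all 3 replicates, and overlap with replicate 1 is not independent of the conservative list either.

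Coordinates are 1-based on dm6. Peak ends stayed within the lengths of the reference sequence of the same assembly on all 7 chromosome arms (X, 2L, 2R, 3L, 3R, 4 and Y). Genes were taken from Ensembl release 115 (BDGP 6.54), with transposable elements and pseudogenes left out of the transcription start sites (TSSs). A summit within 500 bp of any annotated TSS was called TSS-proximal, and a gene with such a conservative summit was called occupied. Other summits were assigned in the order 5' UTR, CDS, 3' UTR, exon of a non-coding gene, intron and intergenic. Peaks on unplaced scaffolds were left out of the comparisons by arm, gene and sequence.

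The tests, lists of genes and sequence words were fixed before the data were examined. Overlap of at least 1 bp between conservative peaks and each replicate's own thresholded list was counted, beside the same peaks moved to random positions of the same arm in 100 draws (20 for positions along genes). TSS-proximal shares of conservative peaks and of failed candidates (below the IDR threshold in the same ranked list) were compared by Fisher's exact test, two-sided. The 33 gene lists were compared with the other protein-coding genes by Fisher's exact test among the 10421 genes on chromosomes 2, 3, 4 and X with a candidate peak in the TSS window. The 7 arms were compared in the same way. The 27 sequence words were searched on both strands within 100 bp of the summit and compared with failed candidates by a Cochran-Mantel-Haenszel test with TSS-proximal and distal strata. P-values were adjusted by the Benjamini-Hochberg method over lists, arms or words, with a threshold of 0.05. Peaks and genes are not replicates, and neighbouring genes can share a peak, so these p-values describe the peak lists; the spread between the 3 replicates' own lists is given as mean ± SD. In the own lists, word shares were set beside those of failed candidates of the same replicate, stratum by stratum, without a test, a choice made after seeing the data. The smallest p written is 1e-300.

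Genes were named by a fixed rule: htk; the 20 conservative peaks of highest signal that overlapped the own lists of all 3 replicates, each named by its nearest TSS; up to 4 members with the highest-signal peak in each gene list past the threshold and up to 2 in each other list; and any member of the Sin3 and chromatin lists. No cells were classified; lists of neuron, muscle, cuticle, germline, gut and fat body, hemocyte and trachea genes served as markers of differentiated types.

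Alternatives covered the other series-level lists, the peaks of highest signal, peaks found in all 3 own lists, leaving aside the own list of each replicate in turn (conservative peaks in both other own lists, which removes no reads of that replicate from the conservative records), TSS windows of 250 and 1000 bp, other gene backgrounds, other overlap rules, word windows of 50 and 250 bp, flanking windows 1000 bp away and strata of GC content in bins of 2 percentage points. Chosen after seeing the data were each replicate's own list for genes and arms, the removal of the 40 kb around htk, GC strata for the TSS-proximal share, keeping only the highest-signal peak of each group of overlapping peaks, and the pooled list for replicate support. Other genes around htk were named after their values were seen. The 95% interval of a difference in summit position came from 1000 bootstrap draws over promoters and was added after the difference was known.

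Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used. The tests were tested on simulated data. With an odds ratio of 4 given to 8 lists in each of 100 draws over 10421 genes, 87.0% of changed lists with 20 or more members and 32.3% of smaller ones were called, against 0.36% of unchanged lists. A DRE word planted in 5% of 4403 shuffled windows was called, and 0 of 25 unrelated words were. The overlap count equalled that of bedtools 2.31.1 (2814 peaks).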

Results

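Hat-trick (htk, FBgn0085451) is the fly relative of mammalian ARID4 proteins, subunits of the Sin3 histone deacetylase complex, and has an ARID and chromo domains. Its binding was mapped in whole embryos of 0 to 24 hours through an eGFP fusion in 3 biological replicates of 1 group. The design allows comparisons of listed peaks with failed candidates or random positions, and between replicates. Failed candidates are called peaks below the IDR threshold and not sites known to be unbound. Of those of the conservative list, 2.80% overlapped the own list of replicate 1. The own thresholded lists held 5484 peaks in replicate 1, 3009 in replicate 2 and 2824 in replicate 3, out of 101552, 87989 and 94826 ranked candidates. The conservative list of the series held 4462 peaks with a median width of 404 bp, 4403 of them on the chromosome arms. Of the 4462 peaks, 1207 overlapped another peak of the same list, so that the list covered 3849 separate places. Signal values are the authors' own values for each peak.

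The first question was how far the replicates shared the conservative peaks. Replicate 1 overlapped 63.1% of the conservative peaks, replicate 2 overlapped 65.3% and replicate 3 overlapped 64.0%, a mean of 64.1% ± 1.13 (SD, n = 3). The lists of all 3 replicates overlapped 1810 peaks (40.6%), and 605 peaks (13.6%) were in none of the own lists. The same peaks at random positions were overlapped by replicate 1 at 2.78%, by replicate 2 at 1.41% and by replicate 3 at 1.28% on average, and by all 3 at 0.69%. Among the 500 conservative peaks of highest signal, 484 (96.8%) lay in all 3 own lists, and the share rose from 3.36% in the third decile by signal to 98.0% in the highest. The lowest decile stood apart at 31.8%; 613 peaks overlapped a peak of higher signal, and their median signal was 26.8. By record match the conservative list compares replicates 2 and 3, so the overlap with these is not independent of how the list was made. The overlap with replicate 1 is not independent either, since the deposited descriptions derive the list from all 3 replicates and its highest signal, 2715, is that of all 4 series-level lists. Overlap between own lists ran from 37.5% of the peaks of replicate 1 found in replicate 3 to 74.8% of the peaks of replicate 3 found in replicate 2, and with a reciprocal overlap of 50% the share of conservative peaks in all 3 lists was 24.1%.

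**Figure D1:**
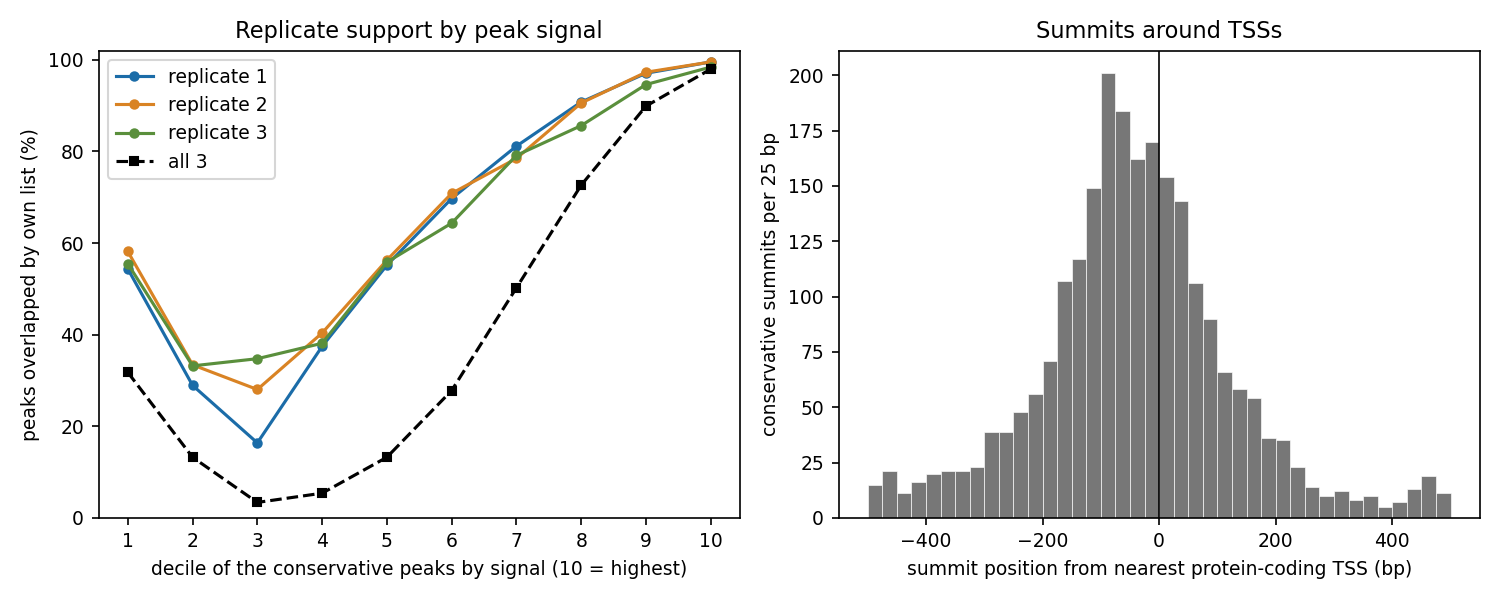
Left, percent of conservative peaks overlapped by the own list of each replicate (coloured lines) and by all 3 (black dashes) per decile of the authors' signal; support by all 3 reached 98.0% in the top decile. Right, number of conservative summits per 25 bp around the nearest protein-coding TSS, with negative positions upstream; the median was -47.0 bp.

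The conservative summits lay mostly at gene starts. Of the 4403 summits on the arms, 2466 (56.0%) were within 500 bp of a TSS, against 15.1% of 116361 failed candidates and 13.5% of random positions (odds ratio 7.17, Fisher's exact test, two-sided, p = 1e-300 or smaller). Introns held 1294 summits (29.4%, against 36.4% of failed candidates) and intergenic sequence 539 (12.2%, against 23.1%). Coding sequence held 28 summits (0.64%), against 21.6% of failed candidates and 13.7% of random positions. The failed candidates thus lay in coding sequence more often than random positions. In the own lists the TSS-proximal share was 60.7% ± 8.79 (SD, n = 3), against 16.5% ± 1.15 (SD, n = 3) of their failed candidates. Replicate 1 had the highest share, 70.6%, with 57.9% in replicate 2 and 53.7% in replicate 3. Conservative peaks were also split by which own lists overlapped them. The share was 62.6% to 78.3% in the groups overlapped by replicate 1 and 33.3% to 41.2% in the groups that were not. The median GC content within 100 bp of the summits was 43.3% in replicate 1, 36.8% in replicate 2, 36.3% in replicate 3 and 47.8% in failed candidates of the conservative list.

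Near protein-coding TSSs the conservative summits lay upstream more often than downstream. Of 2365 such summits, 63.0% were upstream, with a median position of -47.0 bp. Of the 500 conservative peaks of highest signal, 316 had such a summit, at a median of -114.5 bp and with 81.6% upstream. Replicates 2 and 3 had medians of -63.0 and -80.0 bp, while the median of replicate 1 was 21.0 bp downstream with 43.3% of summits upstream.

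The strongest peaks shared by all 3 replicates lay at genes of varied function. The highest signal, 2715, belonged to a peak on X from 2703701 to 2704061 with its summit 37 bp upstream of Ugalt (FBgn0024994), the UDP-galactose transporter. CG14100 (3L, 19590443 to 19590783) followed with a signal of 2513 and a summit 90 bp upstream of its TSS. The third peak, with a signal of 2397, lay in an intron of CG11050 (2L, 6612498 to 6612905), 1020 bp downstream of the TSS. Of the 20 strongest shared peaks, 15 were TSS-proximal, 12 of them upstream. Several sat at genes of mitochondrial ribosomal proteins. The peak at mRpL41 (signal 2096; 2R, 15217593 to 15217927) and that at mRpL23 (1420; 3L, 2373448 to 2373763) were both TSS-proximal. The peaks at Art3 (1759; 3R, 15229373 to 15229703), an arginine methyltransferase gene, and at CenG1A (1675; 2L, 13835297 to 13835623) were also within 500 bp of the TSSs of mRpS10 and mRpS23, and PNPase (1832; 3R, 31404494 to 31404825) encodes a polynucleotide phosphorylase. Tcs5, CG7601, CG5611, CG18549 and px carried TSS-proximal peaks with signals of 2046, 1934, 1694, 1574 and 1395. The peak at the antisense RNA gene asRNA:CR45928 (1755; 2R, 23850233 to 23850564) was within the window of eIF6, a translation factor gene. Chromatin genes among them were the Polycomb gene ph-p (1657; X, 2137182 to 2137526; summit 486 bp upstream) and Chro (1569; 3L, 22878731 to 22879069; summit in an exon, 90 bp downstream), which encodes a chromodomain protein of interbands. The rest lay farther from a TSS, in introns at Adf1 (784 bp downstream), CG32772 (1261 bp downstream) and HmgZ (549 bp upstream), and in intergenic sequence 11912 bp downstream of the TSS of CG13323. All 20 ranked within the top 54 peaks by signal in replicate 1, the top 26 in replicate 2 and the top 22 in replicate 3.

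Around htk itself the conservative list held 10 peaks in 40 kb. A peak from 18843435 to 18843636 on X (signal 446.5) had its summit 119 bp upstream of the htk TSS at which the gene (18843663 to 18855858, plus strand) begins. A further peak from 18848552 to 18848749 (432.2) lay inside htk, 85 bp upstream of shop, a gene on the opposite strand, and within 500 bp of another htk TSS. The others were at CG7101, in Pvf1, at Usp39 and in Dora, genes chosen after these values were seen. The own lists of replicates 1, 2 and 3 held 10, 6 and 12 peaks in the same 40 kb. The failed candidates of this region had a median signal of 46.6 against 25.6 for a typical 40 kb window.

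**Figure D2:**
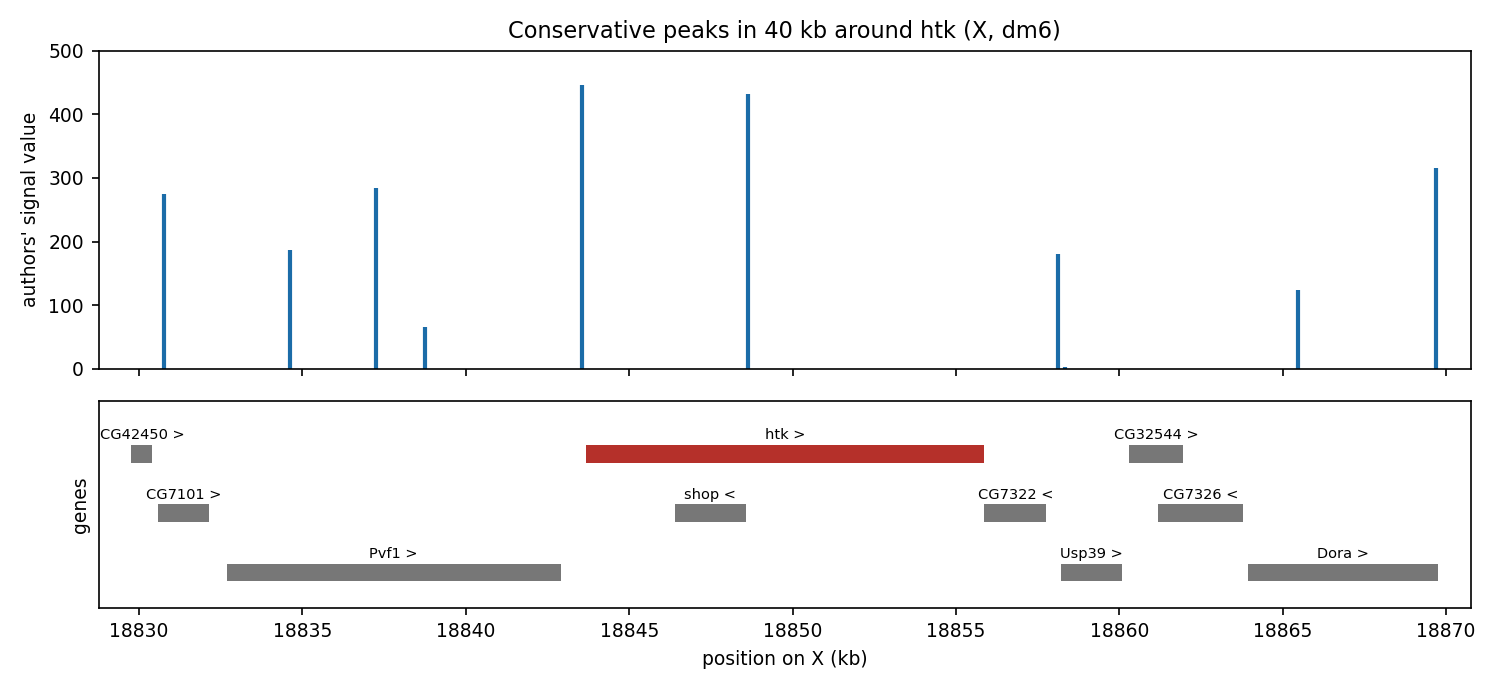
Conservative peaks in the 40 kb around htk on X (dm6). Upper panel, the authors' signal value of each peak at its summit; lower panel, annotated genes with their strand (> plus, < minus), htk in red. The peak at the htk TSS has a signal of 446.5.

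Genes of ribosomal proteins, of the RNA polymerase II machinery, of the trithorax group and of glycolysis were occupied more often than other genes. Of the 10421 tested protein-coding genes, 2663 (25.6%) had a conservative summit within 500 bp of a TSS; the own lists gave 24.8% ± 9.81 (SD, n = 3), and 1365 genes were occupied in all 3 of them. Of 33 gene lists, 4 were occupied more often and 4 less often than other genes at an adjusted p under 0.05 (Fisher's exact test, Benjamini-Hochberg). The samples were whole embryos, not separated by tissue or stage, and an anti-GFP ChIP without the fusion was not used here. How far these differences come from target choice by htk, from the mix of cells and stages or from unspecific signal was not tested. Genes of cytoplasmic ribosomal proteins were occupied in 57 of 79 cases (72.2%, against 25.2% of other genes; odds ratio 7.69, adjusted exact p = 1.35e-16). The share was 64.6% ± 12.2 (SD, n = 3) over the own lists. RpL7, RpL32, RpS27 and RpL34b had the highest signals of the list, 556.5, 520.8, 520.1 and 467.5.

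Genes of RNA polymerase II, TFIID, Mediator and general factors were occupied in 28 of 52 cases (53.8%, against 25.4%; odds ratio 3.42, adjusted exact p = 1.32e-04; 48.7% ± 14.4 in the own lists, SD, n = 3). This call was lost in the own list of replicate 3 (adjusted exact p = 0.052). Polr2B, MED27, Polr2H and Taf5 led with signals of 474.1, 396.4, 345.4 and 315.4. Signals are given per peak, and a peak can lie within 500 bp of TSSs of several genes. That of Polr2B also counts for a gene outside the list. Trithorax-group and remodeller genes were occupied in 12 of 23 cases (52.2%, against 25.5%; odds ratio 3.19, adjusted exact p = 0.0316; 43.5% ± 13, SD, n = 3). The ATPase gene brm had the highest signal (1087), then Ino80 (429.2), Trl (351.5), which encodes the GAGA factor, and ash2 (304.9). The peaks at brm and Ino80 also count for genes outside the list. These signals cannot be assigned to the trithorax genes alone. The trithorax call was lost when only conservative peaks in both other own lists were kept, leaving aside the own list of replicate 1, 2 or 3 (adjusted exact p = 0.435, 0.484 and 0.242), a filter that keeps fewer peaks and removes no reads of a replicate. Over 17 alternatives this p ran from 0.00179 to 0.669. In the own lists of replicates 1, 2 and 3 the trithorax list did not pass (adjusted exact p = 0.143, 0.0759 and 0.530). Genes of glycolysis were occupied in 6 of 9 cases (66.7%; odds ratio 5.84, adjusted exact p = 0.0461), led by Gapdh2 (725.3), Eno (401.5), Ldh (334.9) and Pgk (265.7), and 77.8% were occupied in each own list. With the 5'-most TSS of each gene the glycolysis call was lost, at adjusted exact p = 0.388, and over 17 alternatives this p ran from 0.00234 to 0.388.

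Cuticle, chemoreceptor, gut and fat body, and hemocyte genes were occupied less often than other genes. Single tissues and stages were not profiled, so these shares do not show whether the genes are bound in a few cells. Cuticle protein genes were occupied in 0 of 72 cases (adjusted exact p = 7.94e-09) and chemoreceptor genes in 0 of 108 (adjusted exact p = 2.77e-13), and in the own lists the shares were 0.93% ± 0.80 and 0.31% ± 0.53 (SD, n = 3). Gut and fat body genes were occupied in 1 of 36 cases, Mal-A5, a maltase gene with a signal of 206.5 (adjusted exact p = 0.0029). Hemocyte and immune genes were occupied in 0 of 20 cases (adjusted exact p = 0.0212). The hemocyte call was lost in 9 of 17 alternatives, and at 0 occupied genes with only peaks in both other own lists when that of replicate 1, 2 or 3 was left aside (adjusted exact p = 0.392, 0.421 and 0.220). The gut and fat body call was lost in 6 of 17 alternatives, among them peaks in the own lists of both replicates 2 and 3 (adjusted exact p = 0.252), the list of replicates 1 and 3 (0.148) and the own list of replicate 3 (0.140). The other marker lists did not pass. Their shares were 5.56% (neuron), 6.67% (muscle), 10% (trachea) and 18.2% (germline), also below the 25.6% of all tested genes. With 10 to 18 tested genes each, a lower occupancy of these lists is not excluded. The neuron list had 1 of 18 occupied, elav (681.9), which encodes an RNA-binding protein of neurons (adjusted exact p = 0.172). The muscle list had 1 of 15, sls (373.5; adjusted exact p = 0.264), the trachea list 1 of 10, trh (87.8; adjusted exact p = 0.573), and the germline list 2 of 11, bgcn and gcl (358.4 and 105.9; adjusted exact p = 0.825).

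**Figure D3:**
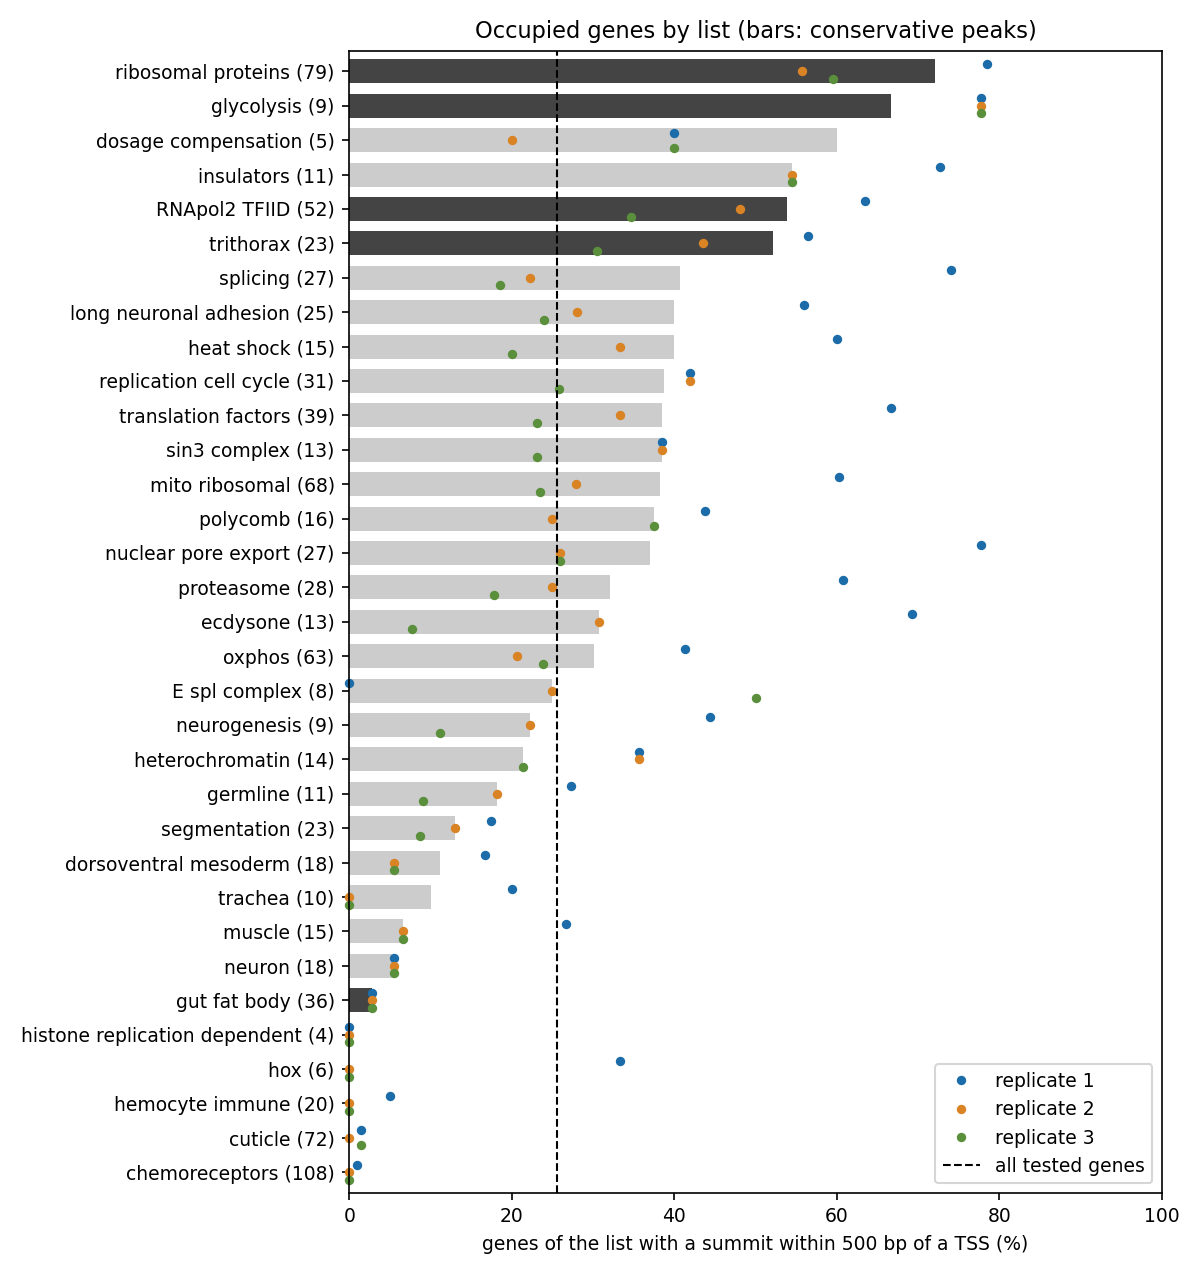
Percent of the tested genes of each list with a summit within 500 bp of a TSS; bars, conservative peaks (dark where the adjusted p was under 0.05), points, the own list of each replicate, dashed line, all tested genes (25.6%). The number of tested genes stands in brackets; ribosomal protein genes reached 72.2% and cuticle genes 0%.

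Chromatin regulators other than the trithorax list did not pass the test. Insulator protein genes were occupied in 6 of 11 cases (54.5%; adjusted exact p = 0.125), among them Chro (1569), Cp190 (451.8), pzg (291.5), BEAF-32 (200.9), pita (144.4) and CTCF (141.3); this list passed in 5 of 17 alternatives, at adjusted exact p from 0.0121 to 0.0444, among them peaks in both own lists of replicates 2 and 3 and of replicates 1 and 2. Polycomb genes were occupied in 6 of 16 cases (adjusted exact p = 0.412), with ph-p (1657) and E(z) (496.0) highest. Of the Sin3 list 5 of 13 were occupied (38.5%; adjusted exact p = 0.479). These were rno (549.7), htk (446.5), the deacetylase gene HDAC1 (238.0), CG7379 (187.8) and CG3815 (137.0). The htk peak lies in the 40 kb where failed candidates also had a raised signal, a median of 46.6 against 25.6. Sin3A, Sap30, Sap130 and MRG15 had no conservative summit in the window. The heterochromatin list had 3 of 14, HP1b and Su(var)3-9 highest (197.1 and 185.6; adjusted exact p = 1), and the dosage compensation list 3 of 5, msl-1 and Sxl highest (171.3 and 125.1; adjusted exact p = 0.226).

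Of the lists for cell growth, mitochondrial ribosomal protein genes were occupied in 26 of 68 cases (38.2%; adjusted exact p = 0.0898), with mRpL41 (2096) and mRpS10 (1759) highest. Translation factors had 15 of 39 (adjusted exact p = 0.187; eIF6, 1755, and eEF1gamma, 404.2), splicing 11 of 27 (adjusted exact p = 0.199; snRNP-U1-C, 413.9, and l(2)k01209, 380.9) and nuclear pore and export 10 of 27 (adjusted exact p = 0.340; Nup37, 520.1, at the peak it shares with RpS27, and Nup160, 278.5). Oxidative phosphorylation had 19 of 63 (adjusted exact p = 0.5; ND-ASHI, 475.9, and ND-MWFE, 300.3), the proteasome 9 of 28 (adjusted exact p = 0.5; Prosalpha3, 247.9, and Prosbeta2, 222.4), replication and cell cycle 12 of 31 (adjusted exact p = 0.226; Dp, 429.8, and Mcm2, 255.8) and heat shock 6 of 15 (adjusted exact p = 0.386; Hsp27, 840.3, and Hsc70-4, 328.8). Several of these lists passed under some of the 17 alternatives: mitochondrial ribosomal proteins in 5 (lowest adjusted exact p = 1.19e-04), translation factors in 4 (2.07e-05; 1 of them peaks in the own lists of both replicates 1 and 2, 0.0259), splicing in 4 (9.84e-06) and nuclear pore and export in 2 (1.55e-04). In the own list of replicate 1 nuclear pore and export genes were occupied at 77.8% against 35.9% of other genes, and at 25.9% against 20.1% in replicate 2 and 25.9% against 18.1% in replicate 3. Splicing genes were occupied at 74.1% against 35.9% in replicate 1, 22.2% against 20.1% in replicate 2 and 18.5% against 18.1% in replicate 3. Among genes with a candidate in replicate 1, 21 of 27 and 22 of 29 of these lists were occupied in its own list (adjusted exact p = 1.55e-04 and 2.41e-04), and the difference between replicates was not tested.

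None of the lists of patterning and developmental genes passed. Segmentation had 3 of 23, nkd and bcd highest (236.4 and 197.0; adjusted exact p = 0.386), the homeotic list 0 of 6 (adjusted exact p = 0.479), and dorsoventral and mesoderm patterning 2 of 18, tin (559.6) and sna (127.4; adjusted exact p = 0.414). Neural fate had 2 of 9, numb (392.2) and N (131.2; adjusted exact p = 1), the Enhancer of split complex 2 of 8, E(spl)m3-HLH (192.5) and E(spl)mdelta-HLH (96.7; adjusted exact p = 1), and ecdysone response 4 of 13, Eip75B and Eip63E highest (263.0 and 201.0; adjusted exact p = 0.825). Neuronal adhesion genes had 10 of 25, PlexA and Dscam1 highest (504.8 and 298.4; adjusted exact p = 0.226), and replication-dependent histone genes, near-identical repeats of which only 4 had a candidate, 0 of 4 (adjusted exact p = 0.681).

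Core promoter words of housekeeping genes were enriched under the TSS-proximal conservative summits. Of conservative summits 47.4% lay within 250 bp of a TSS and 56.0% within 500 bp, against 8.95% and 15.1% of failed candidates. The strata do not match distance to the TSS inside the window. How much of the excess of these words comes from that distance was not tested. The DNA replication-related element DRE (TATCGATA), bound by Dref, was within 100 bp of 6.77% of TSS-proximal summits against 1.89% of TSS-proximal failed candidates (odds ratio 3.54 over both strata, Cochran-Mantel-Haenszel chi-square test, adjusted chi-square p = 1.04e-44). Motif 1, the site of M1BP, was found at 3.33% against 0.95% (odds ratio 3.64, adjusted chi-square p = 6.47e-24) and Motif 7 at 16.1% against 5.53% (odds ratio 2.34, adjusted chi-square p = 2.65e-54). The BEAF-32 site CGATA was in 29.0% of all conservative windows against 19.9% (odds ratio 1.40, adjusted chi-square p = 2.84e-21). It was at 35.9% against 25.2% of TSS-proximal and 20.3% against 18.9% of distal windows. Every DRE word holds CGATA, so its count includes the DRE windows and is not separate from that of DRE. At distal summits DRE was at 0.31% against 0.22%, Motif 1 at 0.155% against 0.0314% and Motif 7 at 3.51% against 3.70%, lower than in failed candidates. In the own lists DRE was found at 7.05% ± 1.02, Motif 1 at 3.12% ± 0.087 and Motif 7 at 15% ± 3.98 of TSS-proximal summits (SD, n = 3), against 2.16% ± 0.249, 1.12% ± 0.119 and 6.17% ± 0.56 of the TSS-proximal failed candidates of the same replicates (SD, n = 3).

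In all, 22 of 27 words passed, 15 more and 7 less frequent than in failed candidates. AT-rich words were among the first, with AATATTAA at 5.18% against 1.75% (odds ratio 2.96, adjusted chi-square p = 2.63e-51), the A tract AAAAAAAA at 13.6% against 8.19% (odds ratio 1.85, adjusted chi-square p = 3.21e-40) and the homeodomain site TAATTA at 13.9% against 8.84% (odds ratio 1.77, adjusted chi-square p = 1.86e-34). With failed candidates matched on GC content 14 words passed, 10 more and 4 less frequent. The calls of CAGCTG (odds ratio 0.85 without and 1.21 with that match, adjusted chi-square p = 0.0027 and 0.0012) and of the CTCF word (0.89 and 1.41, adjusted chi-square p = 0.0467 and 1.41e-08) turned from less to more frequent. DRE (odds ratio 2.18), Motif 1 (2.57), Motif 7 (2.41) and CGATA (1.26) were more frequent with and without that match, AATATTAA fell to an odds ratio of 1.21 (adjusted chi-square p = 0.0361), and the calls of the A tract (0.94, adjusted chi-square p = 0.266), TAATTA (0.92, adjusted chi-square p = 0.157), the TATA box (0.91, adjusted chi-square p = 0.399) and Motif 6 (1.31, adjusted chi-square p = 0.290) were lost. The GAGA repeat of Trl and Clamp had an odds ratio of 1.23 without and 1.68 with that match (adjusted chi-square p = 0.0111 and 3.98e-10). In the own list of replicate 1 it lay at 10.4% of distal summits against 2.76% of failed candidates. Replicate 2 gave 2.95% against 2.45% and replicate 3 gave 2.64% against 2.59%. TSS-proximal shares were 6.28% against 4.71% in replicate 1. They were 4.81% against 4.42% in replicate 2 and 4.28% against 4.21% in replicate 3. The excess of GAGA thus lay mostly in replicate 1. The call of this word, motif GAGA, changed in 7 of 14 alternatives and was lost with only the fewer peaks in both other own lists when that of replicate 1, 2 or 3 was left aside (adjusted chi-square p = 0.842, 0.111 and 0.0755). Of the less frequent words, the Ttk site (odds ratio 0.47, adjusted chi-square p = 7.16e-05) and the CCAAT box (0.86, adjusted chi-square p = 1.20e-05) were called with GC matched too, at odds ratios of 0.63 and 0.86. None of the strata match coding sequence, which held 0.64% of conservative summits and 21.6% of failed candidates. How far this changes the word shares was not tested. Reversed-letter controls also passed, at odds ratios of 2.74 for DRE (adjusted chi-square p = 5.83e-06) and 3.26 for Motif 1 (adjusted chi-square p = 1.20e-05); 18 of the 21 conservative windows with reversed Motif 1 also held Motif 1, and with the match reversed DRE did not pass (adjusted chi-square p = 0.128) while reversed Motif 1 did, at an odds ratio of 2.56 (adjusted chi-square p = 4.00e-04), close to that of Motif 1.

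**Figure D4:**
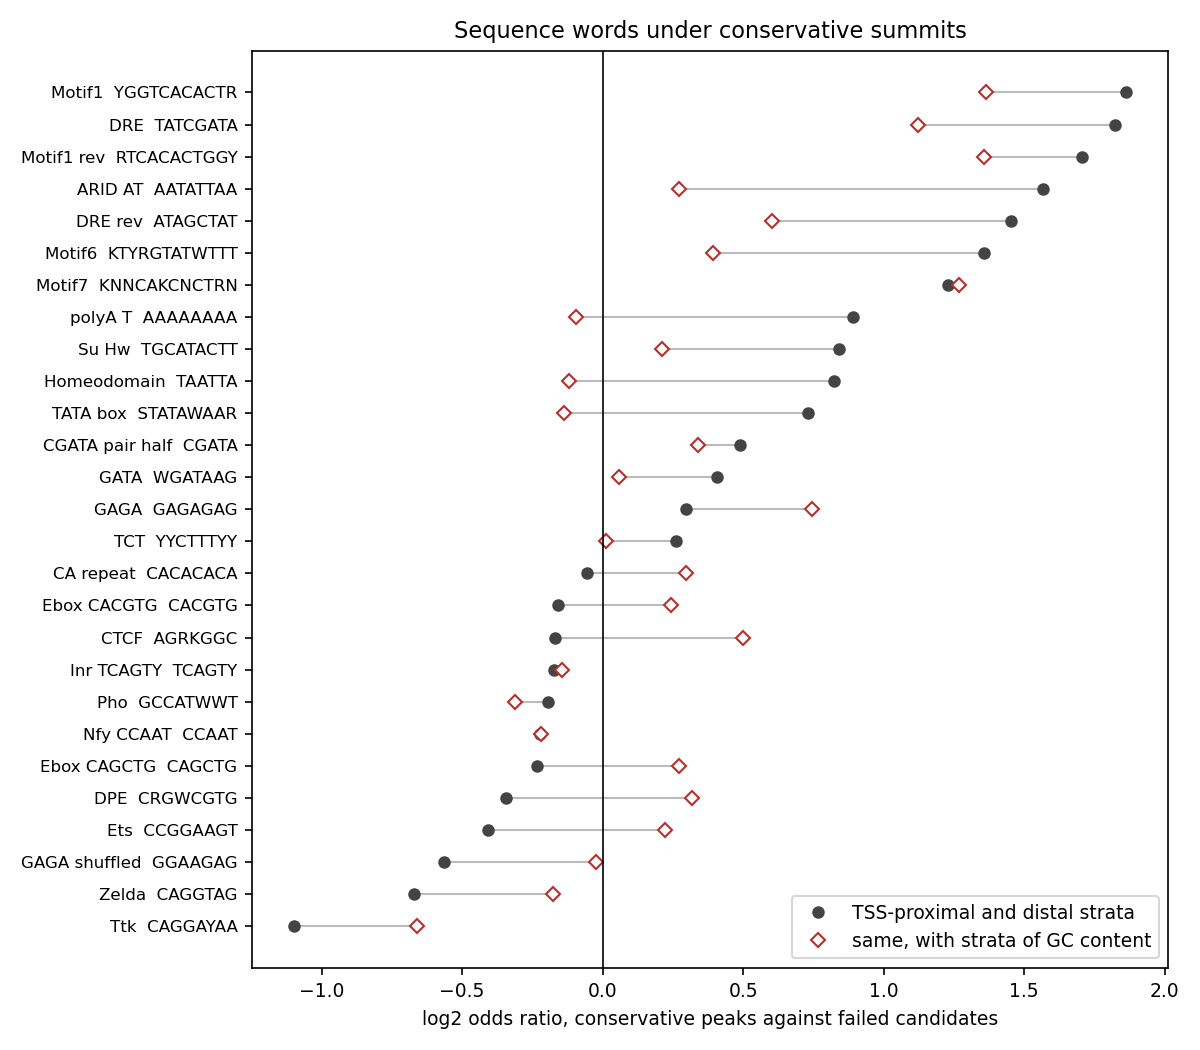
Log2 odds ratio of each sequence word within 100 bp of conservative summits against failed candidates, with TSS-proximal and distal strata (filled circles) and with strata of GC content added (open diamonds); labels give the word and its consensus. Motif 1 moved from 1.86 to 1.36 and the A tract from 0.89 to -0.094.

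Genes on X were occupied less often than genes elsewhere. On X 371 of 1756 tested genes (21.1%) were occupied against 26.4% on the other arms (odds ratio 0.75, Fisher's exact test, adjusted exact p = 1.95e-05). In the conservative list this is a share of genes and not of peaks. X held 813 conservative peaks on 23542271 bp and 2L held 804 on 23513712 bp. The 59 conservative peaks on scaffolds assigned to X were left out. In the own lists of replicates 1, 2 and 3, X held 781, 542 and 530 peaks and 2L held 1002, 555 and 510. The list of replicates 1 and 2 held 662 on X against 751 on 2L. That of replicates 1 and 3 held 529 against 564 and the pooled list 1202 against 1346. The copy number of X in these embryos was not analysed, and no alternative changes it. Over all annotated protein-coding genes the own lists gave 21.9% on X against 29.8% elsewhere in replicate 1, 12.8% against 15.6% in replicate 2 and 11.3% against 14% in replicate 3. Genes on 3L were occupied more often (565 of 1987, 28.4%, against 24.9%; odds ratio 1.2, adjusted exact p = 0.0039), a call lost in 1 of 17 alternatives, the peaks above the median signal (adjusted exact p = 0.102). Chromosome 4 passed with 4 of 5 tested genes (adjusted exact p = 0.0394), but only 5 of its 80 protein-coding genes had a candidate, and with all protein-coding genes as background the direction turned, 5% against 19.1% (odds ratio 0.22, adjusted exact p = 0.0034). The call of arm 4 changed in 12 of 17 alternatives and was lost with only the fewer peaks in both other own lists when that of replicate 1, 2 or 3 was left aside (adjusted exact p = 0.714, 0.715 and 0.300). Arms 2L (27.0%), 2R (24.8%) and 3R (25.8%) did not pass (adjusted exact p = 0.201, 0.460 and 0.681), and on Y 0 of 8 tested genes were occupied (adjusted exact p = 0.302). In some alternatives 2L was called higher (6 of 17, lowest adjusted exact p = 1.22e-05) and Y lower (3 of 16, lowest 0.0325).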

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

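No test was chosen after these results were seen, and none was run on them. Peaks on unplaced scaffolds lay outside all comparisons by arm, gene and sequence, and no control samples were used here. Replicate 2 listed 29 such peaks, replicate 3 listed 44 and the conservative list 59, all on scaffolds assigned to X. Replicate 1 listed 0 of 5484, which allows a share of up to 0.0547% by counting error alone, although 360 of its candidates lay on scaffolds.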

How the results depend on the processing

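The settings chosen after the data were seen are the own list of each replicate, the pooled list for replicate support, the removal of the 40 kb around htk, the highest-signal peak of overlapping groups and GC strata for the TSS-proximal share. That share stayed above its background in all 14 settings, between 47.4% and 66.0%. The lower occupancy of X and the calls of ribosomal protein, cuticle and chemoreceptor genes held in all 17 settings each, and those of DRE, Motif 1, Motif 7, CGATA, AATATTAA and Ttk in all 14. The RNA polymerase II list lost its call in the own list of replicate 3 alone (adjusted exact p = 0.052, from 7.21e-06 to 0.052 over its settings). Lists that did not pass did so in some settings. Called as more occupied were mitochondrial ribosomal proteins and insulators in 5 each and translation factors and splicing in 4 each. So were nuclear pore genes in 2, and ecdysone and replication genes in 1 each. Called as less occupied were neuron genes in 2, and Enhancer of split and histone genes in 1 each. The histone call, at 0 of 111, came with all protein-coding genes as background, although only 4 of these genes had a candidate. Of the other calls, glycolysis changed in 6 of 17 settings (adjusted exact p from 0.0023 to 0.388), trithorax and hemocyte in 9 each (0.0018 to 0.669 and 0.0080 to 0.421) and gut and fat body in 6 (1.71e-05 to 0.252). Of arms, 4 changed its call in 12 settings (adjusted exact p from 0.0034 to 0.866), 3L in 1 (up to 0.102), and 2L and Y gained one in 6 and 3. Of words past the threshold, CAGCTG, Su(Hw) and Zelda changed in 11 of 14 settings each, the CTCF word in 9, GAGA in 7, its rearranged control in 6, GATA in 5, the initiator and TCT in 2 each and 7 others in 1 each. Read depth is unknown, so what it limits was not tested.

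The share of conservative peaks in all required own lists was 24.1% with reciprocal overlap of 50%, 33.2% with summits within 100 bp, 67.7% for the peaks above the median signal, 23.1% for the pooled list, and 46.2% to 52% without a replicate, where peaks had to lie in the other 2 own lists only; this leaves its reads in the conservative records. Gene lists past the threshold numbered 5 with the list of replicates 1 and 3, 14 with the pooled list, 5 with the peaks above the median signal, 5 with a window of 250 bp and 4 in the own list of replicate 3, against 8; they numbered 12 with all protein-coding genes as background and 12 in the own list of replicate 1. Words past the threshold numbered 14 with GC matched and 14 to 17 without a replicate (14 without replicate 3), against 22. The pooled list holds more peaks, and the list of replicates 1 and 3, the peaks above the median signal, the own list of replicate 3 and the sets without a replicate hold fewer; otherwise the cause was not tested.

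Directions turned for these results that passed in either setting, as log2 odds ratios, and the cause was not tested. Chromosome 4 gave -2.17 with all protein-coding genes and -0.15 in the own list of replicate 1, where 2R gave 0.21. With GC matched, CAGCTG gave 0.27, the CTCF word 0.50, the CA repeat 0.30, the TATA box -0.14, TAATTA -0.12 and the A tract -0.094. With the list of replicates 1 and 2, CAGCTG gave 0.086 and the CA repeat 0.40; with the pooled list these gave 0.12 and 0.51 and the CTCF word 0.015. Flanking windows gave CAGCTG 0.10, the CTCF word 0.093 and GATA -0.17. A window of 50 bp gave GAGA -0.093 and the CTCF word 0.021, and one of 250 bp gave the CA repeat 0.47. In the own list of replicate 1, CAGCTG was at 17.7% of TSS-proximal summits against 12.3% of failed candidates. It was at 12.3% against 13.3% in replicate 2 and at 12.9% against 12.9% in replicate 3. Distal summits held it less often than failed candidates in all 3 own lists. The CA repeat was more frequent than in failed candidates in replicate 1 only, in both strata. Signs of results that passed in neither setting turned in 13 cases for arms, 33 for gene lists and 19 for words, among them DPE, Ets and CACGTG with GC matched (0.32, 0.22 and 0.24).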

Other observations

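Chosen only after the result was seen were both tests on 40 kb windows around htk, the rank of AATATTAA among words of A and T, and the bootstrap interval of the summit offset of replicate 1. Genes of tRNAs, snoRNAs and other non-coding RNAs were occupied less often than protein-coding genes. Of tRNA genes with a candidate, 9 of 142 (6.34%) had a conservative summit in the TSS window, against 25.6% of protein-coding genes; the hypothesis that tRNA genes are occupied more often was not borne out (odds ratio 0.20, Fisher's exact test, p = 4.62e-09). Of snoRNA genes 19 of 143 (13.3%; Fisher's exact test, p = 4.65e-04) and of other non-coding RNA genes 168 of 2081 (8.07%; p = 1.67e-80) were occupied, while snRNA genes, at 4 of 15 (26.7%; p = 1), did not pass.

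Summits in annotated transposable elements were rare. Of conservative summits 11 of 4403 (0.25%) lay in such an element, against 1.02% of failed candidates (odds ratio 0.24, Fisher's exact test, p = 4.02e-09), and the own lists held 7, 5 and 8. The authors' further filter, of unknown nature, took 222 of 4684 records past the IDR threshold out of the conservative list. Failed candidates did not go through it. This comparison therefore cannot tell a lack of binding in such elements from removal of peaks there by that filter. DRE and Motif 1 were hypothesised to mark separate occupied promoters; 5 TSS-proximal conservative windows held both, 162 only DRE, 77 only Motif 1 and 2222 neither, which did not bear that out (odds ratio 0.89, Fisher's exact test, p = 1).

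The 10 conservative peaks in the 40 kb around htk were more than most windows with as many promoters held, since 2803 windows with a like number of TSS clusters held a median of 1 peak and at most 13, and the htk window ranked at the 99.7th percentile; 41 of all windows held as many, and 1 of the 10 peaks, of signal 2.55, overlaps the peak at Usp39. The failed candidates of the window had a median signal at the 99.8th percentile of 13367 windows. A raised level across weak candidates as well as peaks is consistent with extra copies of the region carried by the transgene, which remains a hypothesis because neither the inserted sequence, which the labels only place at htk, nor read coverage was analysed here. Binding of the fusion protein to its own gene stays open too, and no test here separates it from copy number.

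Replicate 1 differed from replicates 2 and 3 in TSS-proximal share and summit position. Its longer list does not account for the share, which was 74.2% among its 2824 peaks of highest signal, and weighting to the GC content of replicate 2 left it at 66.4%, so composition may account for part of the gap only. At 664 promoters with a summit in all 3 own lists the median summit of replicate 1 lay at -38.5 bp (58.9% upstream), 23.5 bp downstream of the nearer of the other medians, and promoter by promoter it lay a median of 10.8 bp downstream of the mean of the others (61.9% further downstream). The first value is past the 20 bp set in advance as excluding that different promoters made the offset, but its 95% bootstrap interval, 13 to 36.5 bp, added once the value was known, reaches below this bound, and the second value is smaller, so that explanation is left open. The peaks of replicate 1 were also wider, with a median of 404 bp against 310 bp in replicate 2 and 296 bp in replicate 3. Whether peak width bears on the summit offset was not tested. All replicates belong to 1 group, so no biological explanation was tested.

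AATATTAA was searched because htk has an ARID domain, a fold known to bind AT-rich DNA. Its excess may come from base composition, since it ranked at the 72.8th percentile of 136 words of A and T by enrichment, and strata of GC content lowered its odds ratio from 2.96 to 1.21, between the bounds set for and against GC content as the whole cause. A preference of htk for this word is therefore not separated from a general excess of A and T under the summits.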
